A study of Mus musculus with 4 samples.

How the data were processed

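The series holds 4 droplet single-cell RNA libraries of mouse thymic epithelial cells, KO and WT at E15.5 and at 4 to 6 weeks, with 1 library in each of the 4 groups. The values used are whole-number UMI counts per gene and barcode, deposited by the authors as a sparse table with gene and barcode lists for each library. Reads were processed with Cell Ranger 2.1.1 against mm10, per the submitters' processing notes, and the kit was a 10x Chromium 3' kit of the second version, per the labels. The deposited counts list 32285 genes for every library, with gene lists of 3 columns, which fit a later Cell Ranger and reference than those named, so the versions are given only as stated. In these tables the lowest barcode total was 500 to 503 UMIs, so the tables were already filtered to barcodes. How barcodes were called, how cells were dissociated or sorted, which part of Klf6 was deleted and which Cre line was used are not given in the sources used here. The pools of animals behind each library are not given either.

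Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. The mitochondrial limit was exceeded by 595 barcodes of Adult KO (25.2%), 424 of Adult WT (17.9%), 1682 of E15 KO (24.3%) and 1708 of E15 WT (28.9%). Doublets were scored per library with Scrublet in scanpy 1.11.5 (expected rate 5%), and the highest-scoring 0.8% per 1000 barcodes were removed, 33, 36, 290 and 198 cells. A median of 14574 and 10218.5 UMIs per cell in Adult KO and Adult WT, and 21344.5 and 22387 in the E15 libraries, set the precision of values per cell. Levels in epithelial cells rest on 30423577, 22537112, 111465241 and 93557161 summed UMIs.

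Cells of both genotypes were clustered together for each age, with no batch integration. Counts were scaled to 10000 per cell and logged, and 2000 variable genes were used, leaving out mitochondrial, ribosomal, haemoglobin and sex-linked genes and Klf6. Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) used 30 principal components, 15 neighbours and resolution 1.0. Only the markers for cell types were fixed before the data were examined. The scoring rule and its thresholds were set after looking at the scores of clusters. A cluster took the name of its best list when the mean log2 level of the markers, with an offset of 10 CPM, exceeded the mean over clusters by at least 1. At least 3 markers had to be above 10 CPM and 1 log2 unit over that mean, and no other list was allowed more genes among the 10 leading genes. A cluster also stayed unnamed when its cells' median UMI count was below 33.3% of their library's and none of its list's markers was among the leading genes. Other clusters stayed unnamed. A non-epithelial name also required a pan epithelial score below -1, and all other clusters counted as epithelial, which left 1712, 1848, 4942 and 3991 epithelial cells.

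Gene positions were taken from GENCODE M21 on mm10, which matched 32235 of the 32285 genes by identifier. For each library the UMIs of epithelial cells were summed and divided by their total to give CPM. The comparisons were KO against WT at each age, KO against WT within each named class with at least 50 cells in both libraries, and E15 against adult in WT with the KO pair beside it. The KO to WT ratios of both ages were correlated over genes with at least 50 CPM at both ages. With 1 library per group no test was made and no p-value was computed. Exact Poisson intervals were used for CPM, exact conditional binomial intervals for ratios, and Clopper-Pearson intervals for shares, all at 95%. For list medians, 95% intervals came from 1000 Poisson redraws of the counts. A fold against 0 UMIs was computed against a floor of 3 counts over the group.

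Genes were named by a rule fixed before the data were examined. Klf6 came first. For each comparison, the 12 genes with the highest and the 12 with the lowest ratio were taken among genes with at least 50 CPM in the higher library, and within classes the 6 highest and 6 lowest. Predicted genes, clone names, mitochondrial, ribosomal, histone and receptor segment genes, sex-linked genes and members of non-epithelial marker lists were left out. For a list, up to 4 members of at least 20 CPM with the largest log2 ratio were eligible. Genes common to both ages were up to 10 with at least 1.5-fold the same way at both. Dcn, Epcam, the sex-linked genes and the leading genes of single clusters were named after their values were seen. Cdkn1a, Ccng1, Mki67, Ctsl and Ccl21a by chromosome 13 range were also picked then.

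Gene lists were also fixed beforehand, covering the KLF family, reported KLF6 targets, MHC class I and II, thymocyte support, TEC identity, non-canonical NF-kB, immediate early genes, heat shock, the unfolded protein response, cell cycle phases, kinase inhibitors, p53 response, the BCL2 family, TGF-beta, Notch and Wnt signalling, keratins, matrix, interferon, glycolysis, cholesterol, autophagy and Aire-dependent antigens. A list's value was the median log2 ratio of members with at least 5 CPM on average. It was placed among 10000 random lists of genes drawn within 200 ranks of each member's mean level. Cell type marker lists were treated alike, and lists with fewer than 3 measured members gave no median. Lists can share members, as the p53, kinase inhibitor and KLF6 target lists share Cdkn1a.

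The level of chromosome 13 beyond Klf6 was a choice made after the data were examined, as were its ranges, the Foxn1 limit of 20 CPM and the set of Dcn-led clusters. For each cell the share of UMIs from genes of 5 to 2000 CPM was divided by the mean share of the 30 nearest WT cells, in principal components made without chromosome 13 genes. Ranges were set at 0.25, at 0.75, and at 0.25 above the WT level of 1. The same was done for every other autosome. Positions were summed in bins of 10 Mb over genes of at least 15 CPM in WT. These sums were set against all WT epithelial cells of the age, at E15 outside the Foxn1-low clusters.

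The CPM ratios, the list percentiles and the chromosome 13 ranges were tested on simulated data, and clustering, naming, doublet removal and the correlation were not. Counts were drawn from the real means with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold, among 5501 genes in the adult and 5040 at E15. All changed genes (100%) ranked among the 200 with the largest absolute log2 ratio, and their direction was not scored. The intervals covered the planted ratio in 92.5% to 97.0% of genes. Of 200 unchanged lists, 10 in the adult and 9 at E15 fell outside the central 95% of random lists. WT cells given 0.5 or 2 times their chromosome 13 level fell in the right range in 98.0% to 99.9% of cases. At an unchanged level the 90.1% in the adult and 98.3% at E15 are the shares observed in WT. At a level of 0 the outcome was fixed in advance. KO cells with few similar WT cells, as in clusters drawn almost only from 1 library, were not covered.

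Alternatives fixed beforehand were all deposited barcodes, a stricter filter (at least 1000 genes and 2000 UMIs, at most 5% mitochondrial), no doublet removal, a doubled doublet share, resolutions 0.5 and 2.0, and epithelial cells chosen by Epcam and Ptprc. They also covered TMM scaling (edgeR 4.0.16), median-of-ratios scaling, totals without mitochondrial, ribosomal and haemoglobin genes, the mean of per-cell CPM, cells thinned to 3000 UMIs, class means weighted equally, and list and correlation limits of 1, 50, 20 and 200 CPM. Those chosen after the data were examined were clustering without chromosome 13 genes, leaving out those genes, cells within 0.25 of the WT level, leaving out the Foxn1-low clusters, 10 nearest WT cells, and leaving out of each library the cell with the most UMIs of each gene. Thinning left out 46, 82, 42 and 49 cells. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.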

Results

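Thymic epithelial cells (TEC), which support and select developing T cells, were profiled by droplet single-cell RNA sequencing from mice labelled as Klf6 knockout (KO) or wild type (WT), on the B6129S strain background. The libraries were made from embryos of stage E15.5, called E15 here, or at 4 to 6 weeks of age (adult). Each of the 4 groups holds 1 library, so no difference has a replicate check and cells are not replicates. The deposited tables held 2357 barcodes in Adult KO, 2365 in Adult WT, 6928 in E15 KO and 5915 in E15 WT. The total counts of unique molecular identifiers (UMIs, 1 per captured transcript) were 32292993, 24142066, 122451773 and 101707559. After filtering, 1714, 1888, 4942 and 3991 cells remained, with a median of 14574, 10218.5, 21344.5 and 22387 UMIs per cell. Levels are given as CPM, a gene's share of the UMIs summed over a library's epithelial cells, scaled to the same total in every library. Intervals cover counting error only, and those of levels, ratios of levels and shares are exact 95% intervals. Those of list medians hold 95% of Poisson redraws of the counts. For a difference or quotient of such values, the ends of both intervals were combined, which gives no exact interval.

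The level of Klf6, a zinc finger transcription factor and the gene named in the KO labels, was compared first as a check of the labels. In the adult libraries Klf6 was lower in KO, and it was still detected there at a high level. In the E15 libraries it went against the label over all epithelial cells, although it was lower in the KO library within the cortical cells. The part of the gene deleted in the KO allele is not given in the sources used here. A 3' tag that lies outside that part checks nothing.

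Klf6 (ENSMUSG00000000078, chromosome 13, 5861482 to 5870394, mm10) had 418 CPM in Adult KO against 851 CPM in Adult WT. The ratio was 0.491 (0.481 to 0.503). The adult ratio was 0.572 in the Aire mTEC-like class, 0.343 in the Ccl21a mTEC-like class and 0.672 in the cortical TEC-like class. In the library labelled E15 KO Klf6 had 24.3 CPM against 21.7 CPM in the library labelled E15 WT, a ratio of 1.12 (1.05 to 1.18). Without the clusters that expressed little Foxn1, a set chosen after the data were seen, the direction was reversed (0.829). In E15 cells with a WT-like level of chromosome 13 genes, within 0.25 of that of similar WT cells and with those clusters kept, the ratio was 1.77. Within E15 classes the ratio was 0.703 (0.644 to 0.768) in cortical TEC-like, 0.832 (0.690 to 1.0) in Ccl21a mTEC-like and 1.40 (1.09 to 1.81) in keratinised mTEC-like cells. Because Klf6 over all epithelial cells went against the E15 label, the E15 libraries are called by their labels throughout.

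The sex-linked genes also differed between the E15 libraries. Xist, which is transcribed from the inactive X chromosome of female cells, had 628 CPM in the library labelled E15 KO and 227 CPM in the library labelled E15 WT, against 0.755 and 1.09 CPM in Adult KO and Adult WT. Ddx3y, on the Y chromosome, had 2.03, 22.4, 78.0 and 82.9 CPM in the same order. The E15 libraries thus differed in their share of female and male RNA, and both adult libraries held almost only male RNA.

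The composition of the libraries was compared to see which kinds of epithelial cell each one held. Cortical TEC drive early T cell selection. Cells named cortical took a larger share of Adult KO than of Adult WT cells, mostly in a cluster led by no cortical marker. They took a smaller share of the library labelled E15 KO than of the library labelled E15 WT. Cells of the medullary class named for Ccl21a, a chemokine that draws maturing T cells into the medulla, took a smaller share in both KO libraries. The cluster so named at E15 was not led by Ccl21a, nor was the main one of Adult KO. Tuft cells, which make interleukin 25, were fewer in Adult KO, and medullary cells expressing Aire, the regulator of tissue-restricted antigens, were more. Parathyroid-like cells, marked by the hormone gene Pth, were more in the library labelled E15 KO. Shares can be set by dissociation or sorting, and no sort is described in the sources used here.

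In the adult libraries, cortical TEC-like cells made up 16.2% (14.4 to 18.0) of KO cells against 4.4% (3.52 to 5.42) of WT cells. Aire mTEC-like cells made up 16.2% (14.5 to 18.1) against 6.46% (5.39 to 7.67). Unnamed clusters that scored highest for Aire mTEC but had more genes of another list among their leading genes (2, 8 and 9) held a further 17.9%, 7.64% and 7.64% of KO cells and 5.46%, 2.49% and 2.38% of WT cells. The Ccl21a mTEC-like class made up 9.98% (8.60 to 11.5) of Adult KO and 26.6% (24.6 to 28.6) of Adult WT. It came mostly from cluster 7 in KO (143 of 171 cells, Ccl21a at 744 CPM) and from cluster 1 in WT (460 of 502 cells, Ccl21a at 11045 CPM), so it did not hold the same cells in both. Its shares were 2.0% and 36.3% under a stricter cell filter, and the KO share was 20.1% with coarser clustering. Tuft TEC-like cells made up 0.70% of KO and 2.54% of WT, keratinised mTEC-like cells 2.1% and 4.71%, enterohepatic TEC-like cells 1.23% and 0.106%, and neuroendocrine TEC-like cells 2.33% and 1.38%. Mesenchymal-like cells made up 0.117% and 2.12%, and unnamed clusters took 51.2% and 51.7%. The adult keratinised class, cluster 12, also had Pth and Chga among its leading genes. Of its 36 KO cells, 1 held 9366 of their 9372 Pth UMIs and 3879 of their 3880 Chga UMIs, and its 89 WT cells held no Pth UMI.

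A pair of unnamed adult clusters was led by genes including Dcn, which encodes the matrix proteoglycan decorin. Cluster 0 was also led by Il33, Slfn5, Klf2 and Ackr4, and cluster 5 by Fst, Apoe and Trp63. They had Epcam, the epithelial adhesion gene, at 767 and 564 CPM, and scored highest for mesenchymal and Ccl21a mTEC markers without meeting the naming rule. This set was picked after the data were seen. It made up 3.15% (2.38 to 4.09) of Adult KO and 37.8% (35.6 to 40.0) of Adult WT, or 54 and 713 cells. When clusters were made without chromosome 13 genes, the shares were 3.73% and 34.5%. The WT share was 24.9% with a stricter cell filter, 22.9% with a doubled doublet share removed and 21.0% with finer clustering, with KO shares of 2.90%, 2.32% and 3.09%. In turn, cluster 6, led by Kif19a, Fbxo2 and Gstm1, held 186 Adult KO cells and 4 Adult WT cells. Most of these KO cells had less of the chromosome 13 genes than WT cells, as given in the last comparison. A cluster drawn almost only from 1 library may reflect that library rather than a cell type.

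At E15, cortical TEC-like cells made up 59.6% (58.2 to 61.0) of the library labelled E15 KO and 76.9% (75.6 to 78.2) of the library labelled E15 WT. Clustered without chromosome 13 genes, the shares were 62.0% and 69.1%, and over all deposited barcodes they were 45.7% and 47.9%, a much smaller gap. The cortical markers Prss16 and Ctsl lie on chromosome 13 and stayed in the naming score. They had 20.3 and 80.5 CPM in E15 KO cells with almost none of the chromosome 13 genes, against 865 and 2514 CPM in WT. The E15 cortical shares may therefore depend partly on these markers. Unnamed clusters that scored highest for cortical TEC but below the naming limits held 4.86% and 5.84% (cluster 8), and 5.22% and 0.0251% (cluster 15). Cluster 21, unnamed because its cells had few UMIs and no cortical marker among the leading genes, held 0.526% and none. Ccl21a mTEC-like cells made up 3.08% and 5.06%, keratinised mTEC-like cells 3.76% and 1.83%, parathyroid-like cells 1.90% and 0.702%, and neuroendocrine TEC-like cells 1.86% and 0.727%. The E15 Ccl21a class was cluster 12, led by Il4i1, Pglyrp2 and Srgn and by no marker of its list. It had Ccl21a at 991 CPM and Aire at 51.6 CPM, while cluster 18, named cortical, had Ccl21a at 895 CPM. The name may therefore not fit these cells. Unnamed clusters held 29.8% and 14.8%. Clusters 1, 11, 13, 15 and 21 together held 1809 cells (36.6%) of the library labelled E15 KO and 12 (0.301%) of the library labelled E15 WT, while cluster 20 held 66 cells of the latter alone. Clusters with less than 20 CPM of Foxn1, the transcription factor that drives the thymic fate, held 551 cells (11.1%) and 216 cells (5.41%).

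**Figure D1:**
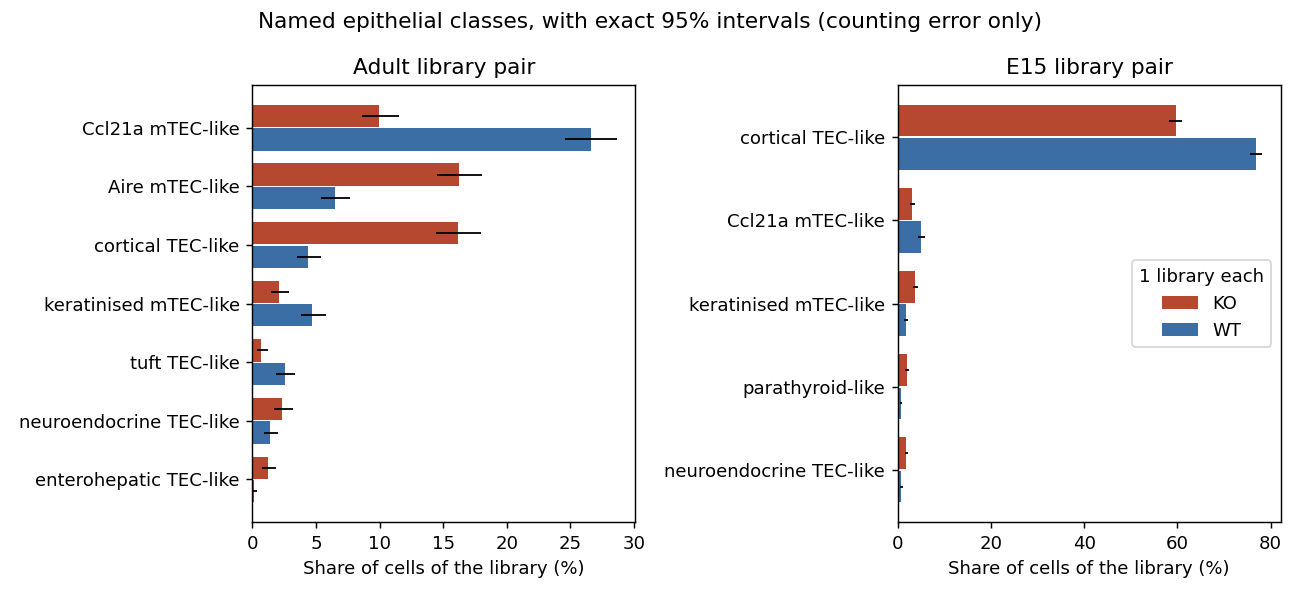
Share of cells (percent, horizontal axis) per named epithelial class, with 1 bar per library and lines for exact 95% intervals of counting error. Cortical TEC-like cells make up 16.2% of Adult KO against 4.4% of Adult WT, and 59.6% of E15 KO against 76.9% of E15 WT. The adult gap lies mostly in cluster 3 (14.1% and 2.81%), which is led by no cortical marker.

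Adult KO and Adult WT epithelial cells were compared to ask how the adult epithelium differed between the labelled genotypes. The genes lower in the KO library included Ccl21a, the attractant of maturing T cells, Ccl11, a chemokine for eosinophils, Fst, an antagonist of activin, and Apoe, a lipid carrier. Trp63, which keeps epithelial progenitors, was lower as well. Interferon-induced genes, KLF family members, and genes for laminins and integrins, which tie epithelium to its basement membrane, were mostly lower in the KO library. The genes higher in the KO library included Igf1, a growth factor, and Aire with several antigens that depend on it, such as the milk casein gene Csn2. Cell division and MHC class II genes were also mostly higher there. Pth and Chga, a granule protein of hormone-secreting cells, stood highest in ratio or close to it, but came mostly from 1 cell. Several of these directions were reversed when each named class was given equal weight, which leaves out the unnamed clusters.

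Ccl21a had 256 CPM in Adult KO and 2918 CPM in Adult WT, 11.4-fold lower (11.1 to 11.7). Pth had 317 CPM and 0.532 CPM, a ratio of 596 (341 to 1154), and Chga was 6.78-fold higher (170 and 25.1 CPM). Of their KO UMIs, 97.0% and 75.0% came from 1 cell, and with the cell holding most UMIs left out, a check made after the data were seen, the ratios were 18.0 and 1.70. Pth UMIs lay in 257 KO cells and the cell with the next most held 7, so the 18.0 rests on few UMIs per cell. Fbxo2, a subunit of a ubiquitin ligase, was 7.29-fold higher (114 and 15.6 CPM). Ckmt1, a mitochondrial creatine kinase, was 5.79-fold higher, and Igf1 3.95-fold higher. Madcam1, Pomc, Itln1, Iapp, Cxcl13, Fabp6 and Rprm were 3.70-fold to 5.82-fold higher. Fst, on chromosome 13, was 9.20-fold lower (16.3 and 150 CPM), and Ccl11 was 7.34-fold lower (44.2 and 325 CPM). Ch25h, Lrmp, Slfn5, Defb1, Sult5a1, Ifi202b, Ifi204 and AY036118 were 5.08-fold to 8.09-fold lower, and Apoe was 4.28-fold lower (402 and 1721 CPM). With equal weight for each named class, the log2 ratios of Cxcl13 (-0.96), Defb1 (0.01) and Apoe (0.40) had the opposite sign.

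For gene lists, the median log2 ratio of KO to WT was set beside its percentile among 10000 random lists of matched size and expression, as a description of these libraries. The median of all genes was 0.04. The interferon response list had a median of -1.07 (percentile 0), with 11 of 14 members at least 1.5-fold lower in the KO library. Ifit1 had 149 and 432 CPM, and Ifit3, its partner in the antiviral response, 82.0 and 231 CPM. With equal class weights this median was 0.01. The KLF family list, which includes Klf6 itself, had a median of -0.77 (percentile 0, 11 of 14 lower), or -0.16 with equal class weights. Klf2 had 197 and 453 CPM and Klf9 had 170 and 374 CPM. The extracellular matrix and integrin median was -0.76 (percentile 0), or -0.17 with equal class weights, with Lamb3 at 16.7 and 44.6 CPM and Itga6 at 128 and 257 CPM. Wnt signalling had a median of -0.53 (percentile 0.16) and TGF-beta signalling -0.49 (percentile 0.03). Reported KLF6 targets had -0.47 (percentile 0.25), where the receptor gene Tgfbr1 was lower (23.5 and 48.0 CPM) and Nos2, the inducible nitric oxide synthase, was higher (40.6 and 16.1 CPM).

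Immediate early genes, which respond quickly to stimuli including dissociation, had a median of -0.41 (percentile 0.03), with Socs3 at 216 and 511 CPM and Atf3 at 1135 and 1947 CPM. Keratins and epithelial junctions had -0.24 (percentile 0.51), with Krt7 at 103 and 267 CPM. With equal class weights these medians were 0.44 and 0.06. Among the higher lists, Aire-dependent and tissue-restricted antigens had a median of 0.77 (percentile 100). Aire had 428 and 182 CPM, Fezf2, a second regulator of such antigens, 369 and 185 CPM, and Csn2 696 and 261 CPM. The S phase list had a median of 0.69 and the G2 and M phase list 0.55, both at percentile 100, with Rrm2 at 46.3 and 17.4 CPM. The p53 response list had 0.43 (percentile 100), cyclin dependent kinase inhibitors 0.43 (percentile 99.2), non-canonical NF-kB 0.41 and the unfolded protein response 0.40 (both percentile 99.8), and MHC class II 0.37 (percentile 99.5). Relb had 223 and 123 CPM, the chaperone gene Calr 1670 and 816 CPM, and Ctss, a protease of class II loading, 159 and 78.8 CPM. With equal class weights the medians of G2 and M phase (-0.30), MHC class II (-0.05) and the kinase inhibitors (-0.07) had the opposite sign.

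Smaller list medians were -0.18 for TEC identity factors, -0.08 for thymocyte support factors, 0.14 for MHC class I, 0.16 for glycolysis, and 0.20 each for heat shock and the BCL2 family. Autophagy, cholesterol and Notch lists lay between -0.00 and 0.06. Within the identity list Foxn1 was higher in the KO library (86.2 and 41.4 CPM) while Trp63 was lower (48.8 and 168 CPM). Il7, which sustains thymocytes, was lower (56.8 and 112 CPM). Among cell type lists, tuft markers had a median of -1.84, with Gng13 at 35.6 and 109 CPM, and Ccl21a mTEC markers -0.59. Aire mTEC markers had 0.89, microfold markers 1.17, enterohepatic 1.23, muscle 1.85 and neuroendocrine 0.43. Cortical markers had -0.01, or 0.27 without the members on chromosome 13. Among these, Ctsl, the lysosomal protease of cortical TEC on chromosome 13, had 570 and 1717 CPM. Keratinised markers had -0.06, pan epithelial markers 0.15, macrophage markers 1.26, mesenchymal 0.43, and pericyte -0.07. Parathyroid (2.76), thymocyte (-0.86) and erythroid (1.88) medians rested on so few UMIs or cells that none remained without the cell holding most UMIs of each gene. Lyz2, a macrophage gene and also a tissue-restricted antigen, had 361 and 154 CPM.

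**Figure D2:**
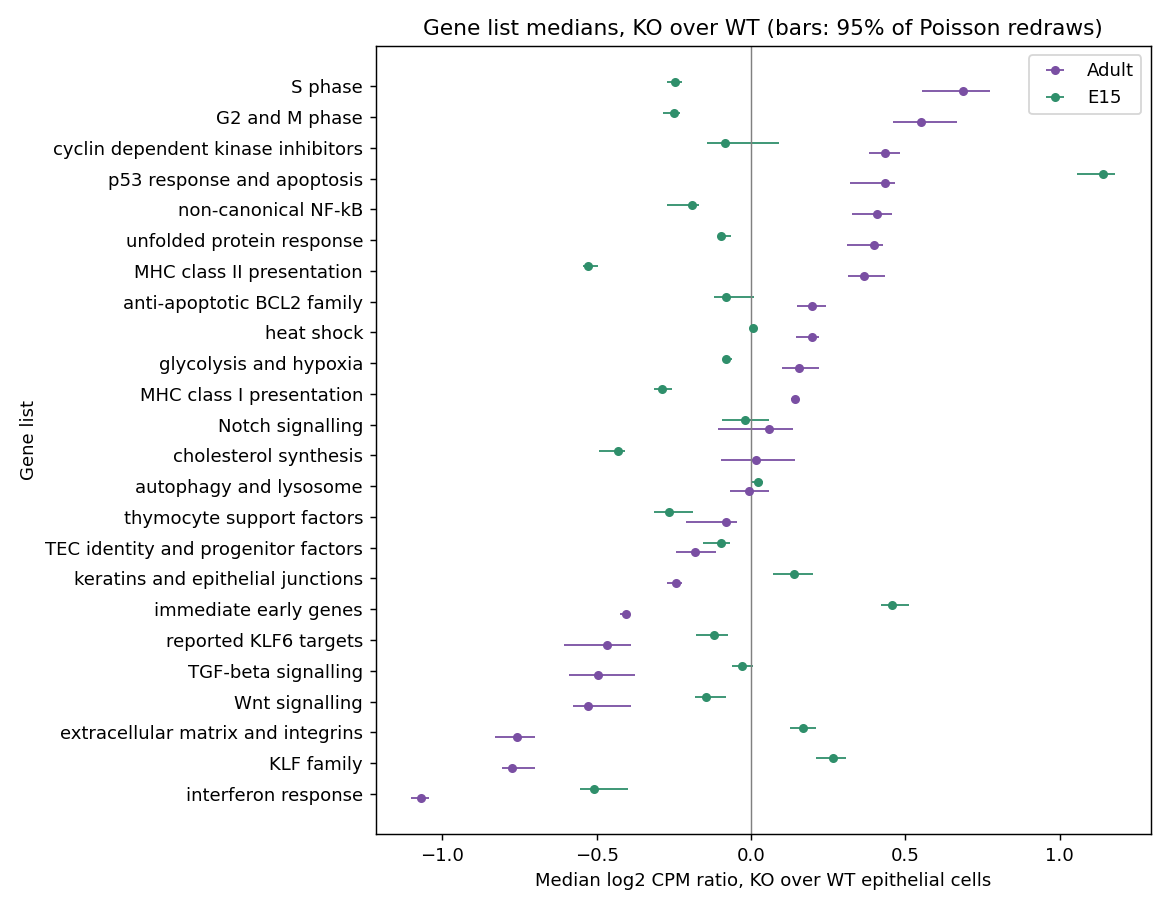
Median log2 ratio of KO to WT (horizontal axis) for each gene list in epithelial cells, with points for the adult and the E15 libraries and lines for 95% of Poisson redraws of the counts. The interferon list lies at -1.07 in the adult and -0.51 at E15, and the p53 response list at 0.43 and 1.14.

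The adult comparison was repeated within classes holding at least 50 cells in both libraries, to separate levels within a class from the shares of classes. In Aire mTEC-like cells the interferon genes were again lower in the KO library, while in the cortical and Ccl21a classes their medians lay near 0. Immediate early genes were higher in the KO library within the cortical and Ccl21a classes, the opposite of the direction over all epithelial cells. The G2 and M phase genes had a slightly lower median within Aire mTEC-like cells of the KO library, against their direction over all epithelial cells. The antigens that depend on Aire went both ways within that class. Gal, the neuropeptide galanin, was lower in that class, where few cells carried it. Krt15, a basal keratin, was higher in the Ccl21a class of the KO library.

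Aire mTEC-like cells (278 cells in KO, clusters 4 and 10 in both libraries) had medians of -1.01 for the interferon list, -0.83 for thymocyte support and -0.22 for the KLF family. Aire-dependent antigens had -0.46 (percentile 0.27), or 0.11 without the cell holding most UMIs of each gene, with 2 of 7 members at least 1.5-fold higher and 2 lower. G2 and M phase genes had -0.26 (percentile 0.02), or -0.22, with 2 of 19 at least 1.5-fold lower and none higher. Ctdspl was 10.5-fold higher (54.4 and 5.17 CPM), Ckmt1 5.45-fold higher, and Bcl2a1b, Madcam1, Igf1 and Unc119 between 3.68-fold and 4.53-fold higher. Gal was 52.0-fold lower (2.67 and 139 CPM), with WT UMIs in 6 cells, or 29.9-fold without the WT cell holding most of them, Igfbp5 6.41-fold lower and Grp 4.96-fold lower. Ppp1r27 was 33.6-fold, Gcg 14.1-fold and Cxcl13 3.41-fold lower, but 1 WT cell held 97.4%, 80.8% and 71.1% of the WT UMIs, and without it the ratios of KO to WT were 1.12, 0.366 and 1.0. The Ccl21a mTEC-like class (171 and 502 cells, mainly cluster 7 in KO and cluster 1 in WT) had medians of 0.63 for immediate early genes, 0.44 for TEC identity and -0.11 for interferon. There Krt15 was 34-fold higher. Bpifa1, a secreted airway defence protein, was 156-fold higher (1652 and 10.6 CPM), but 3150 of its 3210 KO UMIs came from 1 cell, and the ratio was 2.95 without it. Asgr1, Slc16a11 and Gstm1 were 13.4-fold to 26.3-fold higher. Stmn2 had no UMI in KO and 62.3 CPM in WT, at least 40.4-fold lower against a floor of 3 counts, and Skint1, Ccl8, Rgs17, Skint2 and Ptgs2 were 9.07-fold to 14.2-fold lower.

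Cortical TEC-like cells (277 in KO and 83 in WT, clusters 3 and 13 in both, with 36 and 30 cells in cluster 13) had medians of 0.50 for immediate early genes, 0.37 for the p53 response, -0.79 for cholesterol synthesis and 0.10 for interferon. Most KO cells of both clusters had less of the chromosome 13 genes than WT cells, as given in the last comparison. Cck, a gut hormone gene, had 52.7 and 1.75 CPM, a ratio of 30.05 (8.19 to 250.2) that rests on 2 WT UMIs. Fbxo2 was 18.5-fold higher, and Fbln2, Krt19, Sirpa and Kirrel3 were 10.2-fold to 17.2-fold higher. Ccl21a was 6.32-fold lower (57.0 and 360 CPM), or 3.57-fold without 1 WT cell, and Ang, Sfrp1, Lpl, Spon2 and Igfbp7 were 4.73-fold to 8.67-fold lower.

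The library labelled E15 KO was compared with the library labelled E15 WT for the same question before birth. Targets of p53, the transcription factor that stops division or triggers death after damage, were higher in the library labelled E15 KO, among them Cdkn1a, which encodes the cell cycle inhibitor p21. Immediate early genes and Krt7, a keratin of simple epithelium, were higher too. Cell division genes, MHC genes, interferon genes and sterol synthesis genes were mostly lower, as were the cortical genes Prss16, a protease that shapes the peptides presented to T cells, and Dll4, the Notch ligand that commits progenitors to the T lineage. Pth and Chga were higher, carried by the parathyroid-like cells. The direction rests on labels that Klf6 did not bear out over all epithelial cells, and the libraries also differed in the sex-linked genes. The uneven level of chromosome 13 genes, given in the last comparison, went with the labels, being frequent in both libraries labelled KO.

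Cdkn1a had 176 CPM in the library labelled E15 KO and 14.9 CPM in the library labelled E15 WT, a ratio of 11.9 (11.2 to 12.5). Ccng1, another p53 target, was 3.51-fold higher (107 and 30.4 CPM), and Btg2, an antiproliferative gene, 2.88-fold higher (298 and 104 CPM). Bpifa1 was 7.50-fold higher (350 and 46.7 CPM), Chga 6.45-fold (553 and 85.7 CPM), Pth 6.44-fold (1978 and 307 CPM), Ass1 5.39-fold and Krt7 5.15-fold (69.4 and 13.5 CPM). Dcxr, Serpine2, Cox6b2 and Fxyd7 were 2.95-fold to 3.76-fold higher, and the log2 ratio of Fxyd7 was -0.02 with equal class weights. The genes lowest in ratio were closer to 1. Ppp1r27 was 2.46-fold lower (51.3 and 126 CPM), Pcolce2 2.11-fold lower, and Cd83, which stabilises MHC class II on cortical cells, 2.0-fold lower (30.8 and 61.7 CPM). Prss16 was 1.83-fold lower (453 and 830 CPM), Psmb10 1.81-fold lower (411 and 747 CPM), and Cxcl10, an interferon-induced chemokine, 1.79-fold lower. Casz1, Ndrg3, Oma1, Pds5b, Hmgcs1 and Crip3 were 1.70-fold to 1.83-fold lower. Cd83, Prss16 and Hmgcs1 lie on chromosome 13.

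The p53 response list had a median log2 ratio of 1.14 (percentile 100), with 11 of 15 members at least 1.5-fold higher, against an all-gene median of -0.06. Trp53inp1 had 42.7 and 8.48 CPM and Zmat3 29.9 and 13.4 CPM. In E15 cells with a WT-like level of chromosome 13 genes, the median was 0.29. Immediate early genes had a median of 0.46 (percentile 100), with Fos at 182 and 93.5 CPM and Jun at 386 and 223 CPM. The KLF family had 0.27 (percentile 100), with Klf4, a factor of differentiating epithelium, at 22.5 and 12.4 CPM. The keratin and junction list had 0.14 and the matrix and integrin list 0.17, and both had the opposite sign when only members from 50 CPM were used (-0.14 and -0.09). Krt19 had 121 and 47.1 CPM and Sparc, a matrix protein, 173 and 94.8 CPM.

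Among lower lists at E15, MHC class II had a median of -0.53 (percentile 0), with H2-Aa at 222 and 352 CPM and Cd74 at 827 and 1250 CPM. The interferon list had -0.51 (percentile 0), with Iigp1 at 98.3 and 153 CPM, although Ifi27 was higher (37.0 and 23.6 CPM). Cholesterol synthesis had -0.43 (percentile 0), with Fdps at 90.5 and 149 CPM and Hmgcs1 at 66.2 and 113 CPM. MHC class I had -0.29 (percentile 0.05) and thymocyte support -0.27 (percentile 0.06), with Dll4 at 28.0 and 42.2 CPM, Il7 at 239 and 316 CPM and Ccl25 at 801 and 1028 CPM. The G2 and M phase median was -0.25 and the S phase median -0.24, with the proliferation marker Mki67 at 144 and 200 CPM. In cells with a WT-like chromosome 13 level these were 0.03 and 0.01, and the medians of interferon were -0.35, of cholesterol synthesis -0.17, of thymocyte support -0.45 and of non-canonical NF-kB -0.37. Non-canonical NF-kB had -0.19 and Wnt signalling -0.15. The lists of KLF6 targets, TEC identity, the unfolded protein response, glycolysis, BCL2 family, kinase inhibitors, TGF-beta, Notch, heat shock and autophagy lay between -0.12 and 0.02. Among cell type lists, cortical markers had -0.37, with Psmb11, a proteasome subunit of cortical cells, at 315 and 453 CPM. Ccl21a mTEC markers had 0.20, keratinised 0.98, neuroendocrine 2.5, parathyroid 2.69, pan epithelial 0.28 and pericyte markers 0.31.

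Within E15 classes the p53 targets were higher in the library labelled E15 KO in every class that could be compared. Among genes above the CPM limit for naming, Cdkn1a and Krt7 led the cortical cells and Cdkn1a the Ccl21a class. In keratinised cells, which build cornified layers, the interferon-induced chemokine Cxcl10 and the antigen presentation genes were lower in the library labelled E15 KO.

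E15 cortical TEC-like cells (2946 and 3070, mainly clusters 1, 11 and 9 in the library labelled E15 KO and clusters 0, 2 and 5 in the library labelled E15 WT) had a p53 median of 0.96. Their medians were 0.43 for immediate early genes, 0.15 for the KLF family, -0.32 for S phase, -0.38 for G2 and M phase, -0.50 for cholesterol, -0.24 for MHC class II, -0.22 for interferon and 0.03 for MHC class I. The p53 median was 0.33 in cortical cells with a WT-like chromosome 13 level. Cdkn1a was 14.0-fold higher (164 and 11.7 CPM), Krt7 6.58-fold, and Ass1, Dcxr, Ccng1 and Serpine2 3.32-fold to 5.38-fold higher. Ppp1r27, Pcolce2, Fdps, Sgo1, Hmgcs1 and Cd83 were 1.59-fold to 1.91-fold lower.

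Keratinised mTEC-like cells (186 and 73) had medians of -1.29 for interferon, -1.0 each for MHC class I and II, -0.83 for thymocyte support, 0.97 for p53 and 0.39 for G2 and M phase. Ccl5 was 34.6-fold lower (5.54 and 192 CPM), but 278 of its 282 WT UMIs came from 1 cell, and without it the ratio of KO to WT was 2.01. Cxcl10 was 7.53-fold lower (16.2 and 121.7 CPM), and Rgs4, Krt72, H2-Aa and Prss16 3.33-fold to 4.07-fold lower. Anxa3 was 8.25-fold higher, Serpinb3a 5.0-fold and Bpifa1 3.59-fold (8498 and 2366 CPM), with Krt7, Lypd2 and Ass1 at 3.60-fold to 4.09-fold. Ccl21a mTEC-like cells (152 and 202, cluster 12 in both) had medians of 0.90 for p53, 0.70 for kinase inhibitors, 0.50 for immediate early genes and 0.38 for interferon. Cdkn1a was 6.25-fold higher (100.03 and 16.0 CPM), and Slc13a2os, AA467197, Ly6d, Lgals3 and Ccng1 were 3.09-fold to 4.87-fold higher. Vcan, Nop16, Hes6, Prss16 and Bphl were 1.78-fold to 1.90-fold lower. Of these, Vcan, Nop16, Prss16 and Bphl lie on chromosome 13.

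The WT libraries of both ages were compared to describe the epithelium before birth and in the young adult, with the KO libraries beside them. Fetal epithelium expressed more of the fetal genes Hmga2 and H19, a growth regulator and an imprinted RNA, and more of the cortical genes Psmb11 and Dll4. Genes of division and of glycolysis were also higher at E15. The adult WT library expressed far more of Aire, of S100a8, an antimicrobial protein of neutrophils and a medullary antigen, of MHC class I genes and of interferon-induced genes. Immediate early genes such as Fos, and the KLF genes with Klf6 itself, were higher in the adult. Age goes with any difference in preparation between the libraries, and the E15 direction rests on the library labelled E15 WT.

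In WT, E15 over adult, the all-gene median log2 ratio was 0.25 by CPM, 0.67 by TMM scaling, 0.60 by median-of-ratios scaling and 0.41 without mitochondrial, ribosomal and haemoglobin genes. List medians are by CPM and are read against that 0.25, with the value of the KO pair after it. The G2 and M phase median was 2.988 (KO 2.0) and the S phase median 2.32 (1.51), with Cdc20 at 150 and 10.4 CPM. Glycolysis had 1.64 (1.11), with Pkm at 784 and 160 CPM, and cortical markers had 1.08 (1.22), with Psmb11 at 453 and 32.4 CPM, Dll4 at 42.2 and 4.35 CPM and Prss16 at 830 and 192 CPM. Cholesterol synthesis had 0.91 (0.09) and Notch 0.67 (0.82). TEC identity (0.41) and thymocyte support (0.36) lay close to the all-gene median.

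Lower at E15 were interferon genes at -4.83 (KO -3.63), MHC class I at -4.05 (-3.65), immediate early genes at -3.62 (-2.69) and MHC class II at -3.23 (-4.21). B2m, the invariant chain of class I, had 123 and 3686 CPM, Fos 93.5 and 3329 CPM, and Atf3 1.12 and 1947 CPM. Kinase inhibitors had -2.72 (-1.18), the KLF family -2.14 (-1.46), BCL2 family -1.73, keratins -1.19, NF-kB -1.14 (-2.15) and p53 response -1.08 (-0.61). Klf6 had 21.7 and 851 CPM, Klf2 1.12 and 453 CPM, and Klf4 12.4 and 516 CPM. The matrix list had -1.01 (KO 0.10), the unfolded protein response -0.95, KLF6 targets -0.94, autophagy -0.89 and TGF-beta -0.62. Wnt signalling had -0.58, or 0.19 with members from 50 CPM, and heat shock had -0.37 by CPM and 0.05 by TMM. Aire mTEC markers had -6.10, with Aire at 2.66 and 182 CPM, Aire-dependent antigens -7.34, tuft markers -8.44, enterohepatic markers -10.5 and Ccl21a mTEC markers -2.12.

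Hmga2 had 233 CPM at E15 and 2 UMIs in the adult, a ratio of 2622 (725.7 to 21649). Pth had 307 and 0.532 CPM, a ratio of 577, and H19 had 132 and 1.15 CPM, a ratio of 115. Meg3, Ccdc102a and Mfap2 were 60.8-fold to 104-fold higher at E15. Stmn2, a neuronal microtubule regulator, was 36.1-fold higher (617 and 17.1 CPM), Crabp2, which carries retinoic acid, 26.4-fold higher (382 and 14.5 CPM), and Nefm, Nes, Tead2 and Nt5dc2 were 19.3-fold to 26.0-fold higher. S100a8 had 1 UMI at E15 and 332 CPM in the adult. Ly6a, a surface marker of progenitors and interferon-treated cells, had 0.513 and 1276 CPM, and Ccl11 had 0.118 and 325 CPM. Ifi211, S100a9, Ccl7 and Spink1 had no UMI at E15 and were at least 2214-fold lower there. Ccl2 and Mndal had 4 and 5 UMIs at E15, and Ifi203, Ifi204 and Lrmp had 1, 2 and 1.

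The KO to WT ratios of both ages were set against each other to see how far the genotype difference was shared. Serpine2, a protease inhibitor, and Bpifa1 were higher in both KO libraries. So were Pth and Chga, the hormone and granule genes, carried at E15 by the parathyroid-like cells and in the adult mostly by 1 cell. Prss16 and Hpgd, the enzyme that breaks down prostaglandins, were lower in both. Across all genes the relation was weak. The E15 part rests on the libraries labelled E15 KO and E15 WT.

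Over 2151 genes, Pearson's r of the log2 ratios was 0.189 and Spearman's rho 0.0642, across genes, which are not independent replicates. With genes from 200 CPM only, r was -0.0406, and without the cell holding most UMIs of each gene it was 0.0688. The adult and E15 ratios were 596 and 6.44 for Pth and 6.78 and 6.45 for Chga. At E15, cluster 16 (94 and 28 cells) held 98.2% of the Pth UMIs of the library labelled E15 KO and 98.1% of those of the library labelled E15 WT. The ratios were 2.81 and 3.23 for Serpine2, and 2.28 and 7.50 for Bpifa1. They were 2.58 and 2.06 for Unc119, 1.77 and 2.48 for Cd81, 3.051 and 1.73 for Gstm1, and 1.80 and 1.69 for Cyba, a subunit of NADPH oxidase. They were 0.585 and 0.546 for Prss16, on chromosome 13, and 0.265 and 0.597 for Hpgd. The genes of chromosome 13 had a median log2 ratio of -0.21 at both ages (101 and 107 genes).

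Klf6 lies near the start of chromosome 13, and the level of the genes beyond it was followed cell by cell. This comparison was chosen after the data were seen. Many KO cells had a reduced level of these genes, fewer had almost none, and others had more than the WT level. Genes between the centromere and Klf6 were below the WT level in every range of KO cells, and less so than the genes beyond Klf6 only in some ranges. The p53 targets Cdkn1a and Ccng1 were higher in KO cells with less of these genes and in those with more. Mki67, the proliferation marker, was lower in the same cells. In the adult, the p53 list as a whole was not higher in cells with a reduced level than in KO cells near the WT level. The E15 part again rests on the libraries labelled E15 KO and E15 WT.

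Each cell's share of UMIs from chromosome 13 beyond Klf6 was divided by that of its 30 nearest WT cells. In the library labelled E15 KO, 55.1% (53.7 to 56.5) of cells lay more than 0.25 from the WT level of 1, against 1.73% in the library labelled E15 WT. In Adult KO it was 50.9% (48.5 to 53.3), against 9.90% in Adult WT. On the other autosomes the highest share was 2.65% and 1.68% in the E15 libraries, and 18.0% and 14.8% in Adult KO and Adult WT. In the library labelled E15 KO, 573 cells (11.6%) lay below 0.25, 1425 (28.8%) from 0.25 to 0.75 and 725 (14.7%) more than 0.25 above 1. The cells between are called the WT-like range, and the last group the high range. In Adult KO, 31, 696 and 145 cells did so. These ranges are not cell types. Within 0.05 of a boundary lay 372 cells of the library labelled E15 KO, 111 of the library labelled E15 WT, 192 of Adult KO and 173 of Adult WT. None of the 551 cells of the library labelled E15 KO in Foxn1-low clusters lay below 0.25, which allows a share of up to 0.667%. Of these cells, 12.2% (9.55 to 15.2) lay outside the WT-like range, against 60.5% of the other cells of that library. In the library labelled E15 WT it was 7.41% (4.29 to 11.8) in the Foxn1-low clusters and 1.40% in the others. In the adult, 159 of the 186 KO cells of cluster 6 lay from 0.25 to 0.75, as did 198 of 241 in cluster 3 and 27 of 36 in cluster 13, the cortical clusters, and 81 of 143 in cluster 7, the main Ccl21a mTEC-like cluster of KO. In the E15 clusters drawn almost only from the library labelled E15 KO (1, 11, 13, 15 and 21), 69.2% to 96.4% of its cells lay outside the WT-like range. Chromosome 13 genes were used in making the adult and E15 clusters, so these cluster shares are partly set by the clustering itself.

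**Figure D3:**
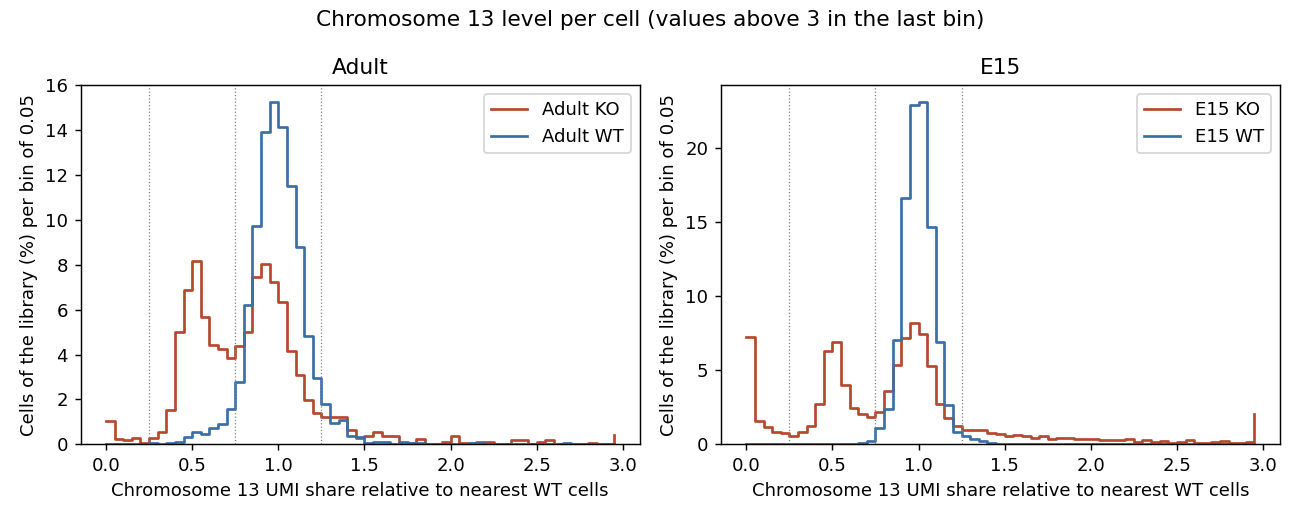
Share of a library's cells (vertical axis, percent per bin of 0.05) by the level of chromosome 13 genes beyond Klf6 relative to the nearest WT cells (horizontal axis, ratio), with 1 line per library and dotted lines at the range boundaries. WT cells centre on 1, while 573 cells of E15 KO lie below 0.25 and 725 in the high range.

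By position, levels were set against all WT epithelial cells of the same age, at E15 outside the Foxn1-low clusters, and not against the nearest WT cells. E15 KO-labelled cells below 0.25 kept 0.495 (0.471 to 0.519) of the WT level for genes between the centromere and Klf6, and 0.0592 beyond Klf6. Cells in the high range had 0.702 and 1.86, cells from 0.25 to 0.75 had 0.649 and 0.504, and cells of the WT-like range 0.875 and 0.982. Adult KO cells below 0.25 (31 cells) had 0.234 and 0.0582, and those of the high range 0.641 and 1.40. From 0.25 to 0.75 (696 cells) they had 0.409 and 0.535, and in the WT-like range (841 cells) 0.592 and 0.837, so there the side of the centromere was the lower. That side rests on 5 genes in the adult and 4 at E15, where Gdi2 alone gave 19335 of the 26993 WT UMIs. In the adult WT-like range, the bin from 60 to 70 Mb, which holds Ctsl, was at 0.421. Ctsl, Prss16, Cd83, Hmgcs1 and Fst all lie on the part beyond Klf6, so their levels include this difference.

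**Figure D4:**
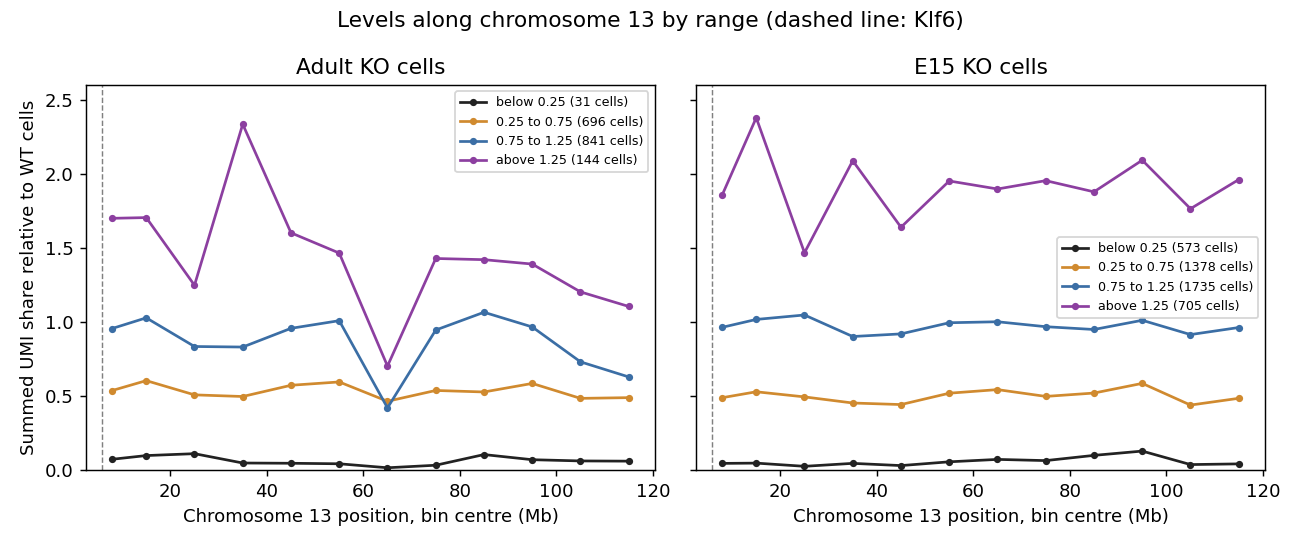
Summed UMI share relative to WT cells (vertical axis, ratio) in bins of 10 Mb along chromosome 13 beyond Klf6 (horizontal axis, Mb), with 1 line per range of chromosome 13 level for KO cells and a dashed line at Klf6. The E15 cells below 0.25, at 0.0592 over all genes beyond Klf6, stay low from Klf6 to the far end.

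Outside the Foxn1-low clusters, the E15 p53 median against WT was 2.03 in cells below 0.25, 1.58 from 0.25 to 0.75, 0.33 in the WT-like range and 1.14 in the high range. Cdkn1a had 421, 237, 62.3 and 283 CPM in these ranges, against 14.2 CPM in WT, and Ccng1 had 214, 151, 52.1 and 146 CPM, against 31 CPM. The interferon medians were -1.11, -0.71, -0.21 and -0.38. The G2 and M phase medians were -1.58, -0.30, 0.10 and -0.59, and Mki67 had 58.4, 116, 189 and 131 CPM, against 200 CPM in WT. Klf6 had 1.98, 13.6, 25.6 and 11.4 CPM, against 20.6 CPM. In the adult the p53 medians were 1.43, 0.17, 0.20 and 0.66, Cdkn1a had 934, 398, 204 and 588 CPM against 226 CPM in WT, and Klf6 had 4.4, 331, 483 and 358 CPM against 851 CPM. Ccl21a had 169, 253, 254 and 302 CPM, below the 2918 CPM of WT in every range.

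**Figure D5:**
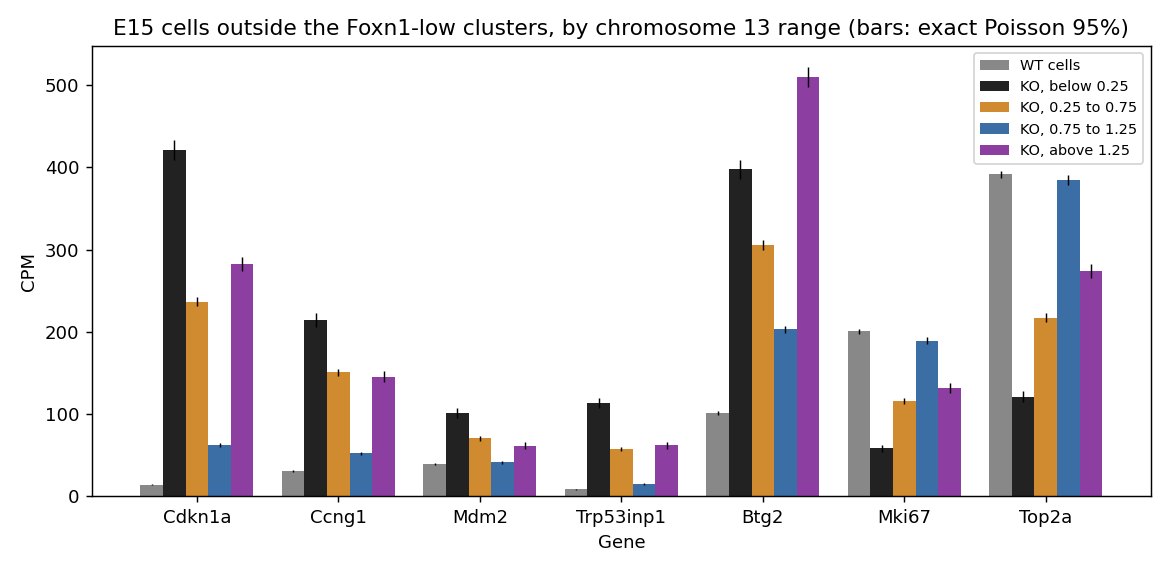
Level (vertical axis, CPM) of 7 p53 target, antiproliferative and proliferation genes in E15 cells outside Foxn1-low clusters, with 1 bar for WT cells and 1 for KO cells of each range of chromosome 13 level, and lines for exact 95% Poisson intervals. Cdkn1a is at 421 CPM in KO cells below 0.25 and 283 CPM in the high range, against 14.2 CPM in WT.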

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

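Each result here stands out because the KO to WT difference went one way in the adult libraries and the other way in the libraries labelled E15 KO and E15 WT. The threshold of 0.2 for the size of each median was set after the results were seen. With 1 library per group at each age, the difference between the ages was not tested.

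KLF family genes, zinc finger factors that include Klf6 itself, had a median log2 ratio of -0.77 in the adult and 0.27 at E15, a difference of -1.04. Immediate early genes, which respond to stress and handling, had -0.41 and 0.46, a difference of -0.86. MHC class II genes, which present peptides to CD4 T cells, had 0.37 and -0.53, a difference of 0.89. S phase genes had 0.69 and -0.24, a difference of 0.93, and G2 and M phase genes had 0.55 and -0.25, a difference of 0.80. The E15 direction holds for the libraries as labelled, since Klf6 over all E15 epithelial cells went against the label. With each named class given equal weight, the adult medians of immediate early genes (0.44), MHC class II (-0.05) and G2 and M phase (-0.30) had the same sign as at E15. Those of the KLF family (-0.16) and S phase (0.12) kept their sign but fell below the threshold. In cells with a WT-like level of chromosome 13 genes, an alternative chosen after the data were seen, the E15 medians of S phase (0.012) and G2 and M phase (0.034) lost the opposite sign.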

How the results depend on the processing

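The alternatives chosen only after the data were seen were clustering without chromosome 13 genes, leaving out those genes, cells within 0.25 of the WT chromosome 13 level, leaving out the Foxn1-low clusters, 10 nearest WT cells, and leaving out of each library the cell with the most UMIs of each gene. E15 values hold for the libraries as labelled. No paired analysis was possible because each group has 1 library. An alternative that leaves a result untouched, such as a scaling for a share of cells, gives no value for it.

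Of 1166 values for 68 named gene results, 854 stayed within the counting interval, 308 lay outside it with the same direction and 4 were reversed. The reversed Klf6 ratio at E15, given below, is not among these 4. Of 1423 values for 74 list results, 1005 stayed within the interval, and 1363 kept their sign. Of 166 values for 26 class shares, 110 stayed within the interval. The order of KO and WT was the same in every setting that gave both shares, such as 7 of 7 settings for adult cortical, Aire and Ccl21a classes and the Dcn-led clusters. Fewer settings gave both shares for the E15 Ccl21a class (3), the adult enterohepatic class (4) and the E15 keratinised class (6).

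With class means weighted equally, the adult log2 medians were 0.011 for interferon, 0.44 for immediate early genes, 0.064 for keratins, -0.045 for MHC class II, -0.30 for G2 and M phase and -0.073 for kinase inhibitors, all of the opposite sign. So were the log2 ratios of Cxcl13 (-0.96), Defb1 (0.011) and Apoe (0.40) in the adult, and E15 keratins (-0.10) and Fxyd7 (-0.023). The Klf6 ratio was 0.426 in the adult and 1.05 at E15, and the correlation of both ages 0.370. This setting leaves out the unnamed clusters and fixes the mix of classes.

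With list members from 50 CPM, where fewer members remained, adult interferon was -0.99 and the E15 p53 median 1.01. E15 keratins (-0.14) and matrix genes (-0.091) were reversed under that limit. In cells within 0.25 of the WT chromosome 13 level, E15 S phase (0.012), G2 and M phase (0.034) and keratins (-0.17) were reversed. There the p53 median was 0.29 at E15 and 0.33 in E15 cortical cells, interferon in the adult -1.58, Klf6 0.569 in the adult and 1.77 at E15, and the correlation 0.221. Without the Foxn1-low clusters Klf6 at E15 was reversed (0.829), the p53 median was 1.23 and the correlation 0.0746. The correlation was reversed with genes from 200 CPM (-0.0406), and was 0.101 with genes from 20 CPM and 0.172 without chromosome 13 genes. The cause was not tested for any of these.

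By TMM, adult interferon was -1.14, adult Klf6 0.468, the WT E15 to adult G2 and M phase median 3.41 and the correlation 0.202. By median-of-ratios, the E15 p53 median was 1.05, Klf6 at E15 1.05, the G2 and M phase median by age 3.34 and the correlation 0.198. Without mitochondrial, ribosomal and haemoglobin genes, the last pair was 3.15 and 0.142. By the mean of per-cell CPM, interferon was -0.83, Klf6 at E15 1.21 and G2 and M phase by age 3.83. With cells thinned to 3000 UMIs, interferon was -0.76, Klf6 0.467 in the adult and 1.43 at E15, the p53 median 0.91 and G2 and M phase by age 3.70. The cause was not tested.

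With the stricter filter, Klf6 in the adult was 0.504, the E15 p53 median 0.97 and 0.91 in cortical cells, and the correlation 0.244. The adult Ccl21a class was 2.0% in KO and 36.3% in WT, E15 cortical cells in KO 61.1%, cells farther than 0.25 from the WT chromosome 13 level in E15 KO 52.97%, and Dcn-led cells in Adult WT 24.9%. With all barcodes the correlation was 0.220, the Ccl21a class 15% and 21.4%, E15 cortical cells 45.7% and 47.9%, their p53 median 1.18, cells farther than 0.25 from the WT chromosome 13 level in KO 56.0% in the adult and 60.3% at E15, and Dcn-led cells in Adult WT 31.4%. With no doublet removal the correlation was 0.220, E15 cortical cells 61.3% and 71.5%, and their p53 median 1.16. With the doubled doublet share the correlation was 0.0685, the Ccl21a class in WT 38.0%, E15 cortical cells 62.3% and 78.7%, and Dcn-led cells 2.32% in KO and 22.9% in WT. The cause was not tested.

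At resolution 0.5 the Ccl21a class was 20.1% of Adult KO, E15 cortical cells 74.8% and 84.7%, their p53 median 1.09, and Dcn-led cells 4.38% of Adult KO. At resolution 2.0 the Ccl21a class was 34.2% of Adult WT, E15 cortical cells 49.0% and 64.4%, their p53 median 1.01, and Dcn-led cells 21.0% of Adult WT. Clustered without chromosome 13 genes, E15 cortical cells were 62.0% and 69.1%, their p53 median 1.13, and Dcn-led cells 34.5% of Adult WT. The cause was not tested.

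Without the cell holding most UMIs of each gene, the adult ratios of Pth and Chga fell, as 97.0% and 75.0% of their KO UMIs came from 1 cell. The correlation was 0.0688 and the G2 and M phase median by age 3.09.

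Depth limits the smallest classes, such as adult cortical TEC-like cells of WT (83 cells), where Cck rests on 2 UMIs, and genes carried by single cells. The ranges of chromosome 13 level are less sharp in the adult, where 9.90% of WT cells lay farther than 0.25 from the WT level, and the cause was not tested.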

Other observations

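The tests chosen only after their results were seen were those of counting noise, of a strain variant or annotation effect of loss or gain and of sex for chromosome 13, those of the Foxn1-low clusters, of the whole library and of chromosome 13 dosage for the p53 targets over all E15 cells, and that of selection of cells.

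Some values belong to no comparison of the report. At E15, cluster 10 was led by Foxe1, Pax8 and Nkx2-1, transcription factors of the thyroid, with Foxe1 at 661 CPM. It held 304 cells (6.15%) of the library labelled E15 KO and 78 cells (1.95%) of the library labelled E15 WT. Cluster 16, the parathyroid-like class, had Pth, the parathyroid hormone gene, at 121108 CPM. Both belong to the Foxn1-low clusters.

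Among adult cell type lists, muscle markers had a median log2 ratio of 1.85, with Acta1, the skeletal muscle actin, at 28.4 CPM in Adult KO, where 1 cell held 43.3% of its UMIs, and 0.577 CPM in Adult WT. Microfold markers had 1.17, with the chemokines Ccl6 at 24.6 and 6.03 CPM and Ccl20 at 83.4 and 34.2 CPM. Macrophage markers had 1.26, while Ptprc, the pan-leukocyte gene, was at 2.53 and 2.23 CPM in the whole libraries. Jag2 and Dll1, Notch ligands, were lower in Adult KO (13.6 and 52.8 CPM, 10.6 and 27.8 CPM), although the Notch list median was 0.06.

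The first pattern is the uneven level of chromosome 13 genes beyond Klf6 among KO cells, with 55.1% of cells of the library labelled E15 KO more than 0.25 from the WT level. Counting noise is argued against by the highest share on another autosome in that library, 2.65% (2.22 to 3.14). A strain variant or annotation effect around Klf6 is argued against by the far end of the chromosome, where genes from 110 to 120 Mb were at 0.0524 (0.0485 to 0.0565) of the WT level in cells picked by other genes. The sex of the animals is argued against as the whole cause. Both adult libraries held almost only male RNA, yet Adult KO had 41.0 percentage points (37.1 to 44.7) more such cells than Adult WT, and at E15 only 1.59% (1.02 to 2.35) of cells of the library labelled E15 WT with Xist and no Ddx3y UMI were so. Loss or gain of the part of chromosome 13 beyond Klf6 remains open. In cells below 0.25 the level between the centromere and Klf6 was 8.35 times (7.83 to 8.90) the level beyond it. These cells were picked by the genes beyond Klf6, so this ratio is partly set by the choice of cells and cannot decide. The values do not show a loss limited to that part, since the level between the centromere and Klf6 was 0.495 of WT in those cells. That level comes mostly from Gdi2 (94.2 CPM against 216 CPM in WT), while Net1 had 31.8 against 37.9 CPM. It is also set against all WT cells outside the Foxn1-low clusters, so it does not decide where a loss would end. In Adult KO cells from 0.25 to 0.75 the level between the centromere and Klf6 was 0.409, below the 0.535 beyond Klf6. That adult pair decides nothing here, because both ratios are to all WT epithelial cells, whose mix of classes differed. Adult KO cells of the WT-like range already had 0.592 and 0.837. Whether such loss may come from the KO allele, a recombinase or another cause was not tested, and genotype stays open as untested.

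The second pattern is the higher p53 target level in the library labelled E15 KO. Cells of the Foxn1-low clusters are argued against as the source, since the median was 1.23 (1.14 to 1.27) without them. A difference of the whole library, such as sex or handling, is argued against as the whole cause, since cells below 0.25 exceeded cells of the WT-like range by 1.70 (1.55 to 1.84). For the smaller median in cells of the WT-like range, 0.33 (0.28 to 0.38), such a difference cannot be told apart. The Foxn1-low clusters had a lower median, -0.026 (-0.17 to 0.18), but they hold other cells, with an unlike mix in each library. Cluster 20 gave 66 of their 216 WT cells and no KO cell, and cluster 10 gave 304 of their 551 KO cells. Altered chromosome 13 dosage remains open as a hypothesis, since cells of the high range also had a high median, 1.14 (1.06 to 1.21), and genotype itself may act beside it, untested.

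The third pattern is the lower Ccl21a level and the smaller share of Dcn-led cells in Adult KO. The cell filters are argued against by a Ccl21a ratio of 0.0902 (0.0881 to 0.0923) over all deposited barcodes. Chromosome 13 genes setting the clusters are argued against by a KO share of 3.73% (2.89 to 4.74) when clustered without them, an alternative added after the data were seen, against 34.5% in WT. Selection of cells in dissociation or sorting cannot be told apart from genotype, since each group has 1 library. Loss of Ccl21a expression and of Dcn-led cells with the genotype may therefore only be offered as a hypothesis, and it stays untested.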
